A study of Mus musculus with 12 samples.

How the data were processed

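RNA was measured in N2A cells, a mouse neuroblastoma line, by sequencing of polyadenylated RNA from stranded libraries. Per the labels, a pair of stable lines carried a doxycycline-inducible, siRNA-resistant, Flag-tagged Puf60 cDNA, with exon 5 in the pEx5 line and without it in the mEx5 line. Cells were transfected with a non-targeting siRNA or a Puf60 siRNA at 15 nM, doxycycline was given at 2 µg/ml for 24 h where stated, and cells were harvested 48 h after transfection. Each of the 6 groups (control, knockdown and induction in each line) held 2 libraries, A and B, described as biological duplicates. Nothing in the labels says whether duplicates came from separate cultures or transfections, and no batch is given, so the p-values measure only the spread between these samples. The sample description of the doxycycline libraries calls them uninduced, against the treatment field; the treatment field was used, and the level and exon 5 content of Puf60 in those libraries match it.

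The deposited splicing table, made by the authors with vast-tools, gave percent spliced in (PSI, in percent) for each of 401633 events in each library. Its quality text, per the file headers and values, also held the corrected inclusion and exclusion reads of each event, and 99.46% of the PSI values lay within 0.02 points of the percentage these reads give. A further deposited table held a group PSI score for each event and group and the authors' True/False call of each event in 7 comparisons, with no stated criterion. The deposited expression table, for which the authors named Salmon 0.14.1 and edgeR with mm10, gave a single rpkm value per gene and group, with the libraries combined. It also held the authors' log2 fold changes for 18600 of 52661 genes in 7 comparisons. Beside them stood the authors' edgeR p-values and the FDR, a p-value adjusted over genes by the authors. The coordinates of the deposited splicing table did not match the mm10 annotation where they were checked, and their assembly is not stated, so positions are printed as deposited.

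The comparisons, the gene lists, the rule for named genes and a splicing test, called the planned test, were fixed before the data were examined. The planned test was limma 3.58.1 in R 4.3.3 on the logit of inclusion reads with a pseudocount of 0.5 reads, 1 coefficient per group, over events with at least 10 reads in each of the 12 libraries. An event was called at a Benjamini-Hochberg adjusted p under 0.05 and a PSI difference of at least 10 points. On simulated data with 2 libraries per group this test recovered 0 of 50 events at each simulated change of 10, 15, 20 and 30 points among 135533 events. Other fits were therefore run on simulated and real data, and 1 was kept for its recovery of simulated changes after the real counts of the fits had been seen. This weighted test uses precision weights from the reads of each event and library, with a variance floor of 0.01, over the 22770 events with a mean PSI of 5 to 95. For knockdown in both lines it recovered 7, 32, 42 and 49 of 50 simulated changes of 10, 15, 20 and 30 points and called 2 of 20207 unchanged events. In a single line it recovered 3, 16, 29 and 43 of 50, with 4 unchanged events called. Few events changed in these simulations, with 135333 of 135533 unchanged before the PSI range was applied. On the real knockdown 28844 of 167832 events had an unadjusted p under 0.05 in the planned limma test. The adjusted threshold was thus stricter in the simulations, which do not measure recovery in the real knockdown. Alternative 3′ and 5′ splice sites were kept as 1 event per alternative site, leaving out the reference site, and a higher PSI means more use of that site. Where an event has several alternative sites, a site can fall as a longer one rises. How introns were read from the table was settled after first results had been seen.

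The expression table held group values and none per library, so the planned count-based tests were not run. Counts of genes for single lines and between control lines are those of the authors' deposited table at an adjusted p under 0.05, and a gene counted for both lines was called in both with the same sign. A limma test on exon-exon junction reads summed per gene was added after the files were seen, for 10363 genes with a mean of at least 20 reads, on log2 CPM of junction reads, scaled by the median of ratios to the geometric mean of libraries, with a prior count of 2. It gave the both-line and isoform-dependent comparisons, all standard errors, and the tests of gene lists. Junction-read totals of a gene can themselves move when its splicing changes. In 10345 genes of simulated data, the test in both lines recovered 42 of 50 simulated 1.25-fold changes and 50 of 50 at 1.5-fold, and called 6 of 10145 unchanged genes. For the 21 gene lists except the mitochondrially encoded one, camera was used with a preset correlation of 0.01 and again with an estimated correlation. Lists are said to pass by camera, which compares the genes of a list with the other genes. A second planned test, fry, asked whether the genes of a list moved, without that comparison. It is given for lists that camera did not pass on knockdown in both lines. The mitochondrially encoded list had too few genes measured on junction reads to be tested. The lists were S phase, G2/M, MYC and nucleolar targets, p53 targets, integrated stress response, unfolded protein response, heat shock, interferon response, immediate early, hypoxia and glycolysis, cholesterol synthesis, nuclear and mitochondrially encoded respiratory chain, neuronal, neural progenitor, glial and fibroblast, neural splicing regulators, hnRNP proteins, SR proteins, U2 and 3′ splice site factors, and nonsense-mediated decay factors.

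The comparisons were knockdown against control in both lines and in each, induction against knockdown in each line, the difference of these inductions between the lines (isoform-dependent induction), and pEx5 against mEx5 controls. The rescue share of a line is the percentage of its median knockdown change that is absent from its median change after induction. Both medians are over events called on knockdown in the other line, with changes signed by their direction there. It is not a median of percentages per event. The change that chose an event thus came from other libraries than the share, while the variance of the call was pooled over all 12. Its 95% interval comes from 10000 bootstrap draws over events. On simulated data, with events called by the weighted test, a true share of 60% was read as 58% and one of 80% as 81.6%. The planned test called 0 simulated events, so shares over planned calls were not tested on simulated data. Intervals of a PSI in 1 library are exact Clopper-Pearson 95% intervals. Sequenced PCR copies are not independent molecules, so these intervals cover counting error only. Exon lengths and flanking introns of called exons were compared with exons that moved by less than 2 points at an adjusted p over 0.5, by permutation tests with 100000 draws, and direction by event type with exact binomial and Fisher's exact tests, all two-sided. Microexons are exons of at most 27 nt.

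Named genes and events follow this rule: the 10 largest changes each way for knockdown in both lines and for isoform-dependent induction and the 5 largest each way otherwise, among calls with the same direction in both replicates, with a mean of at least 5 for genes, leaving out Gm and Rik models, and with 1 event per gene. Of each gene list the rule takes up to 4 called members with the largest change, or the 2 highest where fewer were called. Some genes and events that the rule takes are not reported here. The planned analysis of 3′ splice site sequence was not run because no genome sequence was at hand. Alternatives tried were other read minimums, pseudocounts, scales, size thresholds, weights, the authors' calls, the replicate letter as a block, and leaving out each library. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, or with the R package data.table (version 1.17.8), exact tests used scipy 1.17.1, and plots matplotlib 3.10.9.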

Results

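Polyadenylated RNA was sequenced from 12 libraries of N2A cells, in which the splicing factor Puf60 was depleted with an siRNA and supplied again from an inducible cDNA. Puf60 is an RNA-binding protein related to U2AF that acts at 3′ splice sites. The pEx5 line carried a cDNA with the alternative exon 5 of Puf60, and the mEx5 line one without it. Each line was treated with a non-targeting siRNA (control), the Puf60 siRNA (knockdown), or the Puf60 siRNA and doxycycline (induction), with 2 libraries in each of the 6 groups. No library received doxycycline with the non-targeting siRNA, so the induction comparisons hold the drug and the cDNA together. Libraries A and B of the pEx5 line held 41494994 and 36766280 exon-exon junction reads in control, 35965445 and 36879792 in knockdown, and 27135220 and 26272070 in induction. Those of the mEx5 line held 26772242 and 32981590 in control, 30432733 and 26792582 in knockdown, and 30489955 and 22908930 in induction. Between 259405 and 265619 splicing events per library had at least 10 reads.

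The first comparison asked how far the siRNA lowered Puf60 and what each cDNA put back. Puf60 (ENSMUSG00000002524.17) stood at 308.5 ± 18 CPM of junction reads (SD, n = 2) in pEx5 control libraries, at 61.5 ± 4.3 in knockdown and at 624.4 ± 9.8 in induction. In the mEx5 line it stood at 304 ± 1.5, 73.8 ± 2.5 and 601.8 ± 32.5 CPM (SD, n = 2). On the log2 scale Puf60 changed on knockdown by -2.33 ± 0.059 (SE) in pEx5 and -2.04 ± 0.059 in mEx5 (limma adjusted p = 1.18e-15 and 1.4e-14). Induction raised it by 3.35 ± 0.059 and 3.03 ± 0.059, to 1.02 ± 0.059 and 0.98 ± 0.059 above the controls (limma adjusted p = 5.4e-10 and 7.88e-10). The authors' deposited table gave log2 fold changes of Puf60 of -2.35 and -2.06 on knockdown, and of 3.46 and 3.01 on induction.

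Exon 5 of Puf60 (51 nt, chromosome 15, 75905037 to 75905087) had a PSI of 37.5 ± 2.3% (SD, n = 2) in pEx5 controls, 21.5 ± 2.4% in knockdown and 88.7 ± 1% in induction. In the mEx5 line it had 40 ± 1.1%, 24.4 ± 2.4% and 6.7 ± 0.9% (SD, n = 2). The induced lines thus differed by 82 points in the exon their cDNAs differ in (planned limma test, adjusted p = 0.00398). Inclusion of the exon was lower on knockdown by a change of -15.8 points, which passed the weighted test (adjusted p = 9.9e-05) and not the planned one (adjusted p = 0.0764). With 389 to 3950 reads behind each value, the Clopper-Pearson 95% intervals of the pEx5 libraries were 37.3 to 41% and 33.8 to 37.9% in control and 19.4 to 27.5% and 16.2 to 23.7% in knockdown. Those of the mEx5 libraries were 38.5 to 43.1% and 37.2 to 41.2% in control, and 21.9 to 30.5% and 18.6 to 27.2% in knockdown. Reads of the endogenous transcripts and of the cDNA were not separated.

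**Figure D1:**
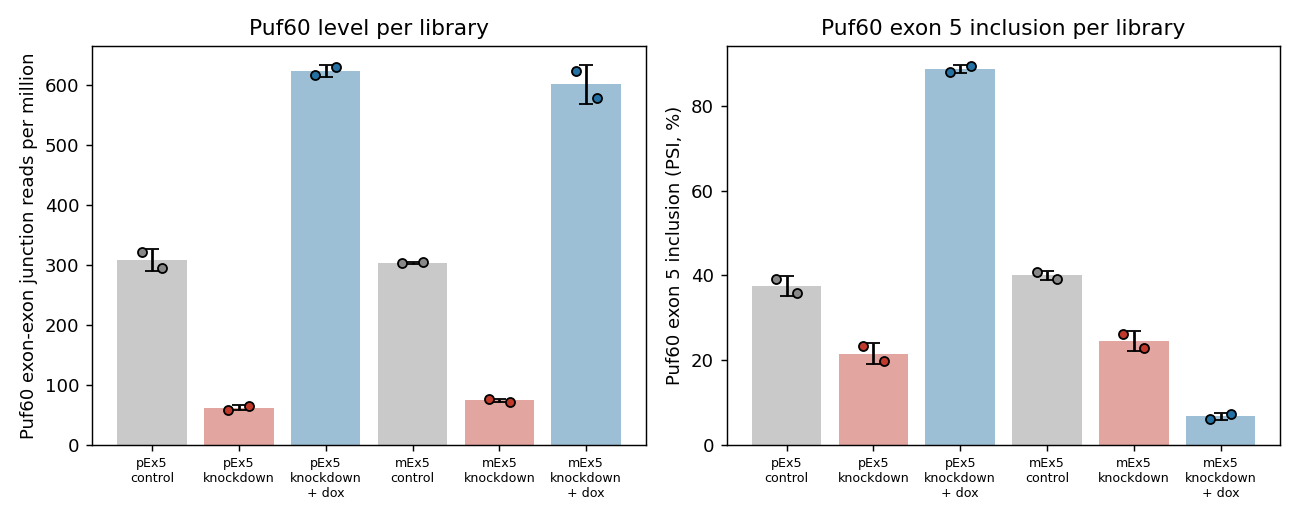
Puf60 level (CPM of exon-exon junction reads) and exon 5 inclusion (PSI, percent) in the 6 groups, with bars for the mean, error bars for the SD and points for the 2 libraries of each group. Puf60 fell on knockdown and rose on induction in both lines, while exon 5 reached 88.7% in induced pEx5 libraries and 6.7% in induced mEx5 libraries.

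Knockdown against control asked which exons and introns depend on Puf60, and the exons it moved were mostly lost. A 9 nt microexon of the neurobeachin gene Nbea (chromosome 3, 55797970 to 55797978), went from 88.5 ± 0.3% to 16.5 ± 2.5% in pEx5 and from 89.9 ± 2.8% to 20.6 ± 4.8% in mEx5 (SD, n = 2; limma adjusted p = 0.000279). A 253 nt exon of the synapsin gene Syn2 (chromosome 6, 115228119 to 115228371) went from 88.9 ± 1.1% to 20.8 ± 2.6% and from 91.9 ± 1.5% to 26.5 ± 1.4% (limma adjusted p = 0.000279). A 156 nt exon of Grip1, which encodes a glutamate receptor scaffold (chromosome 10, 119422530 to 119422685), went from 94 ± 0.4% to 25.3 ± 0.7% and from 95.3 ± 0.2% to 37.8 ± 1.2% (limma adjusted p = 0.000276). An 85 nt exon of Mdm2, the ubiquitin ligase of p53 (chromosome 10, 117146756 to 117146840), went from 79.2 ± 3.2% to 18 ± 1.3% and from 84.1 ± 3.5% to 19.7 ± 1.7% (limma adjusted p = 0.000322). A 90 nt exon of the dystrobrevin gene Dtnb had a mean change of -62.1 points. The other named losses, by mean change in both lines, were in Atp8a1 (-71.9 points), Ttc28 (-71.7), Pfkfb1 (-65.8), Rundc1 (-64.4) and Aldh6a1 (-62.7). Of these, Atp8a1 and Ttc28 had as few as 14 and 11 reads in a library.

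Some alternative sites, introns and exons gained inclusion on knockdown as well. A 3 nt alternative 5′ splice site of the dynactin gene Dctn2 (chromosome 10, 126704475 to 126704538) went from 11.5 ± 4.1% to 83.6 ± 0.3% in pEx5 and from 9.5 ± 0.2% to 78.1 ± 2.8% in mEx5 (SD, n = 2; limma adjusted p = 0.000279). A 448 nt intron of Pnpla6, a lysophospholipase gene (chromosome 8, 3537521 to 3537968), was retained at 21.1 ± 1.5% and 12.9 ± 1.3% in controls and at 78.4 ± 7% and 72.9 ± 6.5% in knockdown (limma adjusted p = 0.00101). A 27 nt alternative 3′ splice site of the ubiquitin ligase gene Rnf111 (chromosome 9, 70290079 to 70290231) went from 6.1 ± 5.9% to 65.6 ± 2.6% and from 4.8 ± 0.7% to 63.7 ± 6.3% (limma adjusted p = 0.000984). A 91 nt exon of Ogdh, a tricarboxylic acid cycle enzyme gene (chromosome 11, 6216768 to 6216858), went from 36.1 ± 1.5% to 86.8 ± 1.4% and from 33 ± 2.1% to 83.7 ± 2% (limma adjusted p = 0.000551). The other named gains were in Tead1 (56.3 points), Fam161a (54.2), Sept8 (52.9), Ccdc45 (51.7), Cox5b (49.3) and Slc8a1 (48.1). Tead1, Fam161a and Cox5b had as few as 11, 12 and 11 reads in a library.

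In both lines together, 2236 of 167832 events passed the planned limma test, 503 with a higher and 1733 with a lower PSI on knockdown. They lay in 1448 genes. Of 55099 exons tested, 123 were higher and 1526 lower, so 92.5% of the called exons lost inclusion. Of 723 microexons, 1 was higher and 75 lower (98.7% lower; exact binomial p = 2.04e-21). Retained introns went the other way, with 263 higher and 40 lower of 84154 (13.2% lower; exact binomial p = 2.17e-41), and the direction differed between exons and introns (Fisher's exact test, adjusted p = 7.64e-181). Alternative 3′ splice sites were 99 higher and 81 lower (exact binomial p = 0.205), and alternative 5′ splice sites 17 higher and 11 lower (p = 0.345), with no direction that passed the planned test. The weighted test called 1152 higher and 2724 lower, of which exons were 316 and 2265, microexons 3 and 122, introns 582 and 168, 3′ sites 178 and 137, and 5′ sites 73 and 32. There the direction of 3′ sites (exact binomial p = 0.0241) and of 5′ sites (p = 7.81e-05) passed, towards higher PSI. Neither passed at 15 points (exact binomial p = 0.0935 and 0.243), and with 1 event per gene only that of 5′ sites did (exact binomial p = 0.143 and 9.34e-05). Alternative sites of the same event are not independent trials. The binomial tests assume that both directions are equally open. An event with a control PSI within 10 points of full or no inclusion can be called only away from it. Of the 167832 events, only 22770 had a mean PSI of 5 to 95. Starting PSI may thus set part of the directions and of the difference between exons and introns, which was not tested. Within that range 87.8% of weighted exon calls and 22.4% of weighted intron calls were lower. Of the 2171 planned calls the weighted test could test, it called 2169. The planned count was 1391 without pEx5 knockdown library A, 1429 without B, 1460 without mEx5 knockdown library A and 1377 without B, where the lone library is assumed to vary like the other groups.

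**Figure D2:**
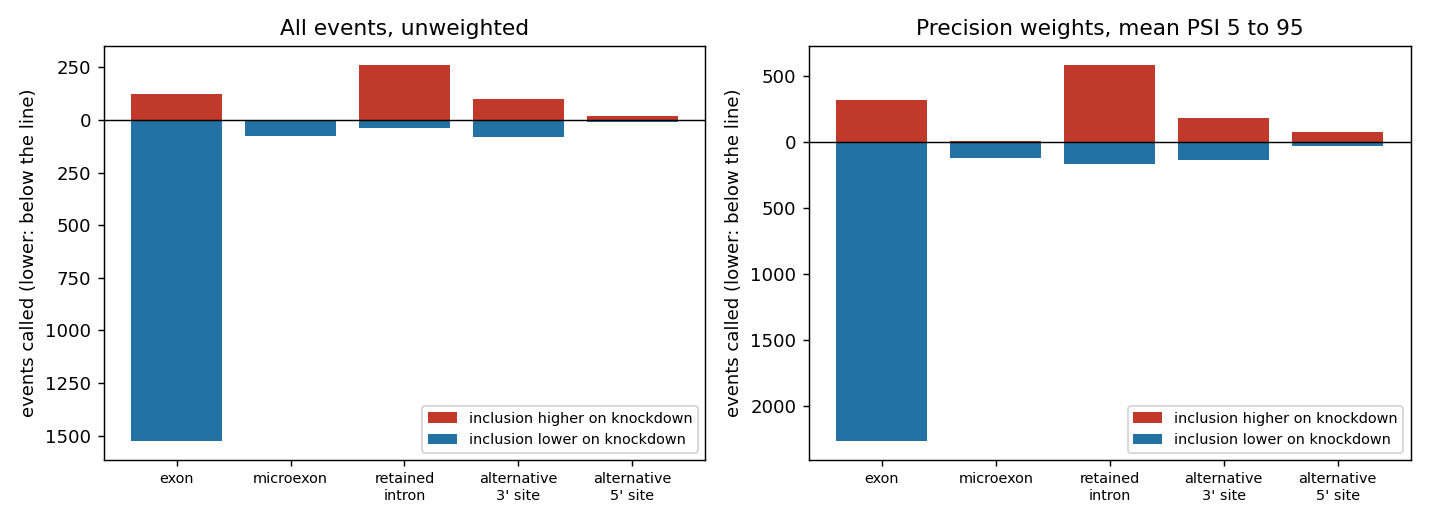
Number of events with higher (up) and lower (down) PSI on knockdown in both lines, by event type, under the planned test and the weighted test. Exons and microexons were mostly lower, 1526 and 75 against 123 and 1 in the planned test, and retained introns mostly higher, 263 against 40.

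Skipped exons were shorter than unmoved ones and lay between longer introns. The 1601 exons that lost inclusion, microexons among them, had a median length of 97 nt against 119 nt in 29892 exons that did not move. Their upstream and downstream introns had medians of 3217 and 2968.5 nt, against 1763 and 1682 nt. The permutation p was 1e-05 for each of these, the smallest the permutations can give (adjusted p = 1.33e-05). Exons that gained inclusion lay between short introns instead, with medians of 599.5 and 546 nt for 124 exons (adjusted p = 1.33e-05), and their median length was 119 nt (permutation p = 0.99; in the weighted test 117 nt against 113 nt, adjusted p = 0.0155). A length divisible by 3 was found in 46.7% of skipped and 38.9% of unmoved exons (Fisher's exact test, adjusted p = 5.93e-09). In the weighted test the shares were 46.9% and 40.7% (Fisher's exact test, adjusted p = 0.000561). Gained exons had a like share, 46.8% (Fisher's exact test, adjusted p = 0.0906), and in the weighted test 50.2% against 40.7% in unmoved exons (adjusted p = 0.00311).

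Events called on knockdown in a line mostly moved in the same direction in the other. In pEx5 the planned limma test called 134 events higher and 716 lower, with Tead1 (74.4 points) and Dctn2 (72.1) highest and Ttc28 (-81.7), Pfkfb1 (-74.2) and Nbea (-72) lowest. In mEx5 it called 97 higher and 570 lower, with Dctn2 (68.5 points) and Ccbl1 (53.5) among the highest and Atp8a1 (-72.9), Nbea (-69.2), Syn2 (-65.5) and Mdm2 (-64.4) lowest. Of 1074 events called in either line, 443 were called in each, all with the same sign. If calls fell independently and evenly over all events, 3.4 would be shared. That number is likely too low, since events differ in how readily they are called and both lines used the same pooled variance. Over the 1074 events 97.9% had the same sign in both lines. Across all 167832 events changes in the lines had a Pearson r of 0.724 and a Spearman rho of 0.341, and across 10363 genes on junction reads an r of 0.84 and a rho of 0.823. Across the 22770 events of the weighted test they had a Pearson r of 0.758 and a Spearman rho of 0.654. There 2043 events were called in each line, against 401.3 for independent and even calls. Events and genes are not independent replicates. The difference of the knockdown changes between lines was called for 0 events by limma, in the planned test (8421 at an unadjusted p under 0.05) and in the weighted one (1215). A count of 0 does not show that the lines responded alike. In pEx5 the count of 850 was 206 without control library A and 144 without B, and 109 without knockdown library A and 116 without B. In mEx5 the count of 667 was 152 without control library A, 190 without B, and 0 without either knockdown library. It was 410, 423, 439 and 440 without pEx5 knockdown libraries A and B and pEx5 induced libraries A and B.

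**Figure D3:**
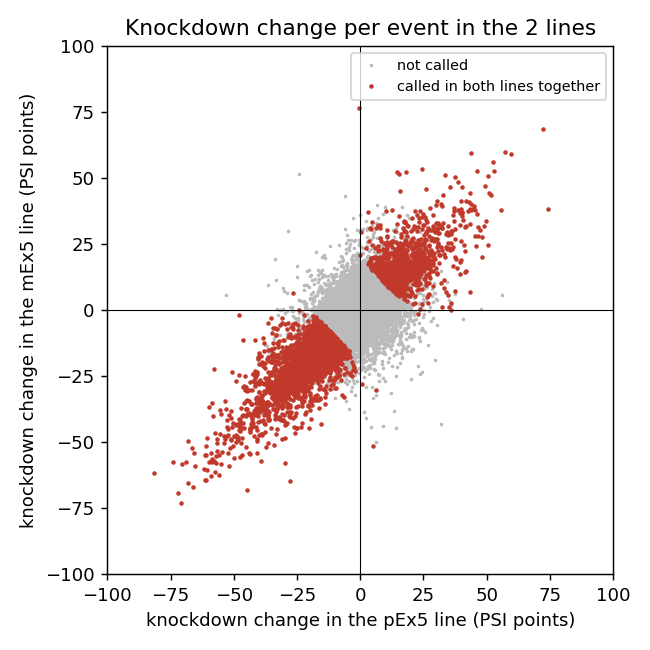
Change in PSI on knockdown (points) in the pEx5 line and the mEx5 line, with 1 point per event of the weighted test (22770 events) and red points for events called in both lines together. The changes lay along the diagonal, with a Pearson r of 0.758 across events.

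In gene expression, knockdown lowered Vamp2 and Sv2a, which act in synaptic vesicle release. Vamp2, a vesicle SNARE (ENSMUSG00000020894.16), changed by -1.98 ± 0.13 on the log2 scale in both lines (SE, n = 2 per group; limma on junction reads, adjusted p = 2.03e-10) and Sv2a by -1.71 ± 0.068 (adjusted p = 2.04e-13). Other named losses, with their values on junction reads, were in Heatr3 (-1.84 ± 0.041), Ptbp2, a neural splicing regulator (-1.82 ± 0.053), Agtpbp1 (-1.7 ± 0.046), Oip5 (-1.69 ± 0.073), Pts (-1.55 ± 0.055), Pigp (-1.47 ± 0.082), Tmem65 (-1.28 ± 0.061) and Adnp (-0.68 ± 0.082). Genes were ranked by the authors' deposited table, where Adnp had larger log2 fold changes, -1.9 in pEx5 and -1.47 in mEx5. Among the gains, Myl9, a myosin light chain gene (ENSMUSG00000067818.6), rose by 2.61 ± 0.093 (limma adjusted p = 5.45e-14). Other named gains were in Ccnb1ip1 (1.95 ± 0.14), Ptgr1 (1.65 ± 0.065), S100a1 (1.53 ± 0.12), Cpne1 (1.51 ± 0.054), Vsig1 (1.45 ± 0.13), Galnt3 (1.4 ± 0.078), Apol10b (1.33 ± 0.087), Dbx2 (1.32 ± 0.11) and Nmi (1.28 ± 0.11). By the authors' deposited table, 2819 genes were higher and 3259 lower on knockdown in pEx5, and 2600 and 3116 in mEx5, of 18600 tested. In that authors' deposited table, 1870 genes were higher and 2550 lower in both lines, of which 305 and 75 changed at least 2-fold in each. On junction reads limma called 2801 genes higher and 2572 lower of 10363 (3150 and 2292 with total junction reads as the scaling), and the knockdown effect differed between lines for 3 genes. Among the largest log2 gains of a single line in the authors' deposited table were also Gstm1 (1.71 in pEx5), Slamf9 (2.21 in mEx5) and Sprr2f (1.85 in mEx5).

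The S phase, integrated stress response, unfolded protein response, cholesterol synthesis and interferon lists passed on knockdown with the preset correlation. None of the 33 measured S phase genes was higher and 27 were lower (0 and 28 adjusted over the list alone), among them E2f1 (-0.98 ± 0.068), Mcm6 (-0.68 ± 0.038), Cdc45 (-0.6 ± 0.043) and Tyms (-0.53 ± 0.053; camera adjusted p = 2.97e-09; adjusted p = 0.0632 with an estimated correlation). Of 29 integrated stress response genes 24 were higher and 2 lower (24 and 2 adjusted over the list alone), among them Trib3 (1.01 ± 0.055), Slc7a11 (1 ± 0.075) and Ddit3 (0.79 ± 0.051; camera adjusted p = 1.16e-08; adjusted p = 0.0632 with an estimated correlation). In the mEx5 line alone both lists passed with either correlation: integrated stress response adjusted p = 6.41e-13 and 0.035, and S phase adjusted p = 4.18e-11 and 0.0437 with an estimated correlation. Of 20 unfolded protein response genes 15 were higher and 0 lower (15 and 0 adjusted over the list alone), with Herpud1 at 0.5 ± 0.036 and Sel1l at 0.43 ± 0.048 (camera adjusted p = 3.17e-05; adjusted p = 0.097 with an estimated correlation). Cholesterol synthesis genes were 1 higher and 12 lower of 19 (1 and 12 adjusted over the list alone), with Insig1 at -0.73 ± 0.089 and Stard4 at -0.55 ± 0.049 (camera adjusted p = 0.000743; adjusted p = 0.263 with an estimated correlation). Interferon response genes were 8 higher and 1 lower of 12 (8 and 1 adjusted over the list alone), with Ddx58 at 0.7 ± 0.13 and Isg15 at 0.64 ± 0.13 (camera adjusted p = 0.0341; adjusted p = 0.263 with an estimated correlation). With the preset correlation the interferon list passed in pEx5 alone (camera adjusted p = 0.0172) and not in mEx5 alone (0.105).

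The hnRNP and neural splicing regulator lists passed as well. Of 17 hnRNP genes 1 was higher and 12 lower (1 and 14 adjusted over the list alone), among them Hnrnpc (-0.76 ± 0.058), Hnrnpa2b1 (-0.52 ± 0.045) and Hnrnph1 (-0.51 ± 0.036; camera adjusted p = 0.000267; adjusted p = 0.263 with an estimated correlation). Of 20 neural splicing regulators 2 were higher and 11 lower (3 and 11 adjusted over the list alone), among them Ptbp2, Elavl2 (-0.85 ± 0.052) and Elavl4 (-0.63 ± 0.042; camera adjusted p = 0.00793; adjusted p = 0.263 with an estimated correlation). Among 23 U2 and 3′ splice site factors 6 were higher and 7 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.894), with Ddx46, a helicase of the U2 particle, at 0.9 ± 0.036, and Sf1 at -0.49 ± 0.033. The median of this list was 0.03 and its mean -0.01. SR proteins were 3 higher and 6 lower of 12 (3 and 6 adjusted over the list alone; camera adjusted p = 0.357). In the authors' deposited table they were 1 higher and 8 lower of 14. On junction reads, nonsense-mediated decay factors were 4 higher and 3 lower of 14 (4 and 3 adjusted over the list alone; camera adjusted p = 0.874), with Smg6 at 0.88 ± 0.055 and Nbas at -0.78 ± 0.047. Neural splicing regulators with skipped exons numbered 3 of 20 in the planned test (Elavl4, Ptbp2 and Rbfox2; Fisher's exact adjusted p = 1) and 9 of 15 in the weighted test (Fisher's exact p = 0.0611, adjusted p = 1).

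The remaining lists that were tested did not pass as groups on knockdown by camera, but some did by fry. The fry adjusted p was 0.000116 for neuronal, 3e-04 for G2/M and 0.000125 for p53 genes. It was 0.00075 for heat shock and for glial and fibroblast genes, and 0.0145 for nuclear respiratory chain genes. Hypoxia (0.056), MYC (0.0569), immediate early (0.113) and neural progenitor genes (0.81) did not pass by fry. Neuronal genes were 4 higher and 10 lower of 29 (4 and 10 adjusted over the list alone; camera adjusted p = 0.0807), with Snap25 at -0.94 ± 0.043 and Gata3 at 0.97 ± 0.091. G2/M genes were 3 higher and 13 lower of 29 (3 and 13 adjusted over the list alone; camera adjusted p = 0.0807), with Ttk at -0.41 ± 0.043. p53 targets were 9 higher and 1 lower of 21 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0807), with Cdkn1a at 0.47 ± 0.059. Heat shock genes were 5 higher and 1 lower of 10 (camera adjusted p = 0.0847), nuclear respiratory chain genes 2 and 9 of 26 (0.0847) with Ndufs1 at -0.87 ± 0.038, and glial and fibroblast markers 4 and 0 of 6 (0.117), with the same counts adjusted over the list alone. MYC and nucleolar targets were 8 higher and 6 lower of 23 (camera adjusted p = 0.638), immediate early genes 4 and 3 of 15 (0.816), hypoxia genes 6 and 5 of 19 (0.874) and neural progenitor genes 4 and 1 of 14 (0.874). Adjusted over the list alone the counts of these lists were the same, but for 2 and 1 neural progenitor genes. In the authors' deposited table the balance of called genes lay the other way for 3 of these lists: MYC and nucleolar targets were 3 higher and 5 lower of 29, immediate early genes 3 and 5 of 23, and neural progenitor genes 0 and 3 of 17. The hypoxia list had a median of -0.05 and a mean of 0.12. Of 13 mitochondrially encoded genes, 0 were higher and 1 was lower in both lines in the authors' deposited table, and this list was not tested as a group.

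Induction against knockdown asked which of these changes each cDNA undid. In pEx5 the Nbea microexon returned to 79.2 ± 4.3% (SD, n = 2; limma adjusted p = 0.0457), the Dtnb exon to 88.4 ± 0.5% (adjusted p = 0.0371), and a 24 nt microexon of Uggt1 went from 65.5 ± 0.4% to 97.3% (adjusted p = 0.0371). A 116 nt exon of the amino acid transporter gene Slc38a2 went from 57.9 ± 2.5% to 93.8 ± 0.5% (adjusted p = 0.0479), and a 385 nt intron of Dhdds from 95 ± 0.4% to 59.5 ± 0.6% (adjusted p = 0.0479). Rundc1 rose by 67.8 points (adjusted p = 0.0495). The planned limma test called 7 events higher and 4 lower in pEx5 (16048 at an unadjusted p under 0.05). The weighted test called 1045 and 266, of which 818 and 133 were exons and 69 and 2 microexons. In both tests the higher events include exon 5 of Puf60, which the cDNA carries (67.2 points, planned limma test, adjusted p = 0.0371). The planned count was 0 without any 1 of the 12 libraries. The weighted count of 1311 was 777 without pEx5 knockdown library A, 736 without B, 856 without pEx5 induced library A and 789 without B.

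In mEx5 the Dtnb exon returned to 86.5 ± 3.5% (SD, n = 2; limma adjusted p = 0.0222), and the Dctn2 site to 18.3 ± 0.9% (adjusted p = 0.022). The Pnpla6 intron returned to 20.4 ± 6.5% (adjusted p = 0.0447), and an alternative 3′ splice site of Ifi27l1 went from 26.4 ± 1.3% to 82.6 ± 1.1% (adjusted p = 0.0217). Atp8a1 (70 points), Zfp942 (55.4) and Dzip1 (55) rose, and Ccdc136 (-46.4), BC018507 (-45.1, with as few as 10 reads) and Elf2 (-43.5) were lower. The planned limma test called 148 events higher and 23 lower, of which exons were 133 and 8. The weighted test called 1573 and 483, with exons 1184 and 244 and microexons 70 and 6. The planned count of 171 was 0 without any 1 of the mEx5 knockdown and induced libraries. It was 99 and 86 without mEx5 control libraries A and B, 94 without either pEx5 control library, 53 and 65 without pEx5 knockdown libraries A and B, and 64 and 65 without pEx5 induced libraries A and B. The weighted count of 2056 was 1218 without mEx5 knockdown library A, 1230 without B and 1298 without mEx5 induced library A. Of the weighted calls 808 were shared by the lines, against 118.4 for independent and even calls, and 806 of the shared calls had the same sign.

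The events that knockdown moved went most of the way back in both lines. Over 667 events called in mEx5, the median change in pEx5 was 21.87 points on knockdown and 4.99 after induction, a rescue share of 77.2% (95% interval 75 to 79.2). Over 850 events called in pEx5, the median change in mEx5 was 20.33 points on knockdown and 2.28 after induction, a share of 88.8% (87.3 to 90.3). Exons had shares of 77% in pEx5 and 89% in mEx5, retained introns 74.4% and 85.2%, and microexons 91.9% (77.5 to 98.6) over 21 events and 88.9% (82 to 92.1) over 36. Over the calls of the weighted test, introns had shares of 52.8% (46.2 to 61.6) in pEx5 and 77.3% (72.4 to 81.2) in mEx5. Microexons had 76% (68.9 to 83.4) and 80.7% (71.6 to 86.6) there, the other order of the lines, with overlapping intervals in both cases. Each induced library showed it, with median distances from control of 4.73 and 4.88 points in pEx5 and 2.34 and 2.1 in mEx5. Induced against control libraries, the planned limma test called 0 events in each line (15336 and 12587 at an unadjusted p under 0.05), and the weighted test 228 higher and 458 lower in pEx5 and 100 and 152 in mEx5. Syn2 was at 51.7 ± 3.7% in induced pEx5 against 75.9 ± 6% in induced mEx5 libraries, and the Mdm2 exon at 56.7 ± 2.3% and 57.2 ± 0.7% (SD, n = 2).

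**Figure D4:**
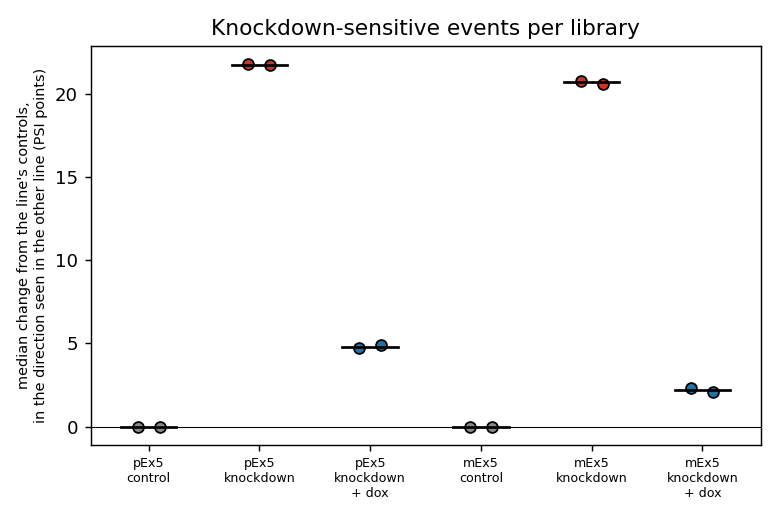
Median distance of each library from the controls of its line (PSI points, in the direction of the knockdown change), over events called on knockdown in the other line, with points for libraries. Induced libraries lay at 4.73 and 4.88 points in pEx5 and at 2.34 and 2.1 points in mEx5, far below the knockdown libraries.

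Vamp2, Sv2a, Snap25, Heatr3 and Ptbp2, lower on knockdown, rose again on induction. Vamp2 rose by 2.02 ± 0.18 in pEx5 and 1.5 ± 0.18 in mEx5 (log2, SE, n = 2 per group; limma adjusted p = 2.1e-07 and 5.04e-06), Sv2a by 1.4 ± 0.096 and 1.43 ± 0.096, and Snap25 by 1.19 ± 0.061 and 0.76 ± 0.061. Heatr3 rose by 1.37 ± 0.058 and 1.65 ± 0.058. Ptbp2 rose by 1.12 ± 0.075 and 1.07 ± 0.075 and stayed below control, by -0.81 ± 0.075 and -0.63 ± 0.075 (limma adjusted p = 2.18e-07 and 5.51e-06). Myl9 stayed above control, by 2.62 ± 0.13 and 1.63 ± 0.13 (limma adjusted p = 1.07e-10 and 4.56e-08). In the authors' deposited table, 1987 genes were higher and 1607 lower on induction in pEx5, and 1988 and 1722 in mEx5. Named there besides these were Blcap (1.5), Fkbp1b (1.27), Pvrl3 (-0.84), Zfp870 (-0.83) and Tle6 (-0.75) in pEx5, and Ccnb1ip1 (-1.11), Ddx46 (-1.08), Rnaseh2c (-1.06) and Rprd1a (-0.93) in mEx5, as log2 fold changes of the authors' deposited table. On junction reads limma called 1321 genes higher and 954 lower in pEx5 and 1363 and 1308 in mEx5, where 1151 of 2379 were higher without mEx5 induced library A. The rescue share over genes called in the other line was 43.8% (41.6 to 45.7) in pEx5 and 61.1% (58.8 to 63.3) in mEx5. The pEx5 junction-read count of 2275 was 1279 without pEx5 knockdown library A, 1124 without B, 1296 without pEx5 induced library A and 1512 without B.

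Several lists passed on induction with the preset correlation. Integrated stress response genes, already higher on knockdown, were again 8 higher and 1 lower of 29 in pEx5 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00111; adjusted p = 0.199 with an estimated correlation). In mEx5 they were 16 higher and 1 lower (19 and 2 adjusted over the list alone; camera adjusted p = 3.78e-05; adjusted p = 0.174 with an estimated correlation), with Ddit3 at 0.32 ± 0.072 and Trib3 at 0.42 ± 0.077. Unfolded protein response genes were 0 higher and 7 lower in pEx5 (0 and 8 adjusted over the list alone; camera adjusted p = 0.00161; adjusted p = 0.199 with an estimated correlation). They were 1 and 12 in mEx5 (1 and 14 adjusted over the list alone; camera adjusted p = 2.63e-05; adjusted p = 0.174 with an estimated correlation). Cholesterol synthesis genes were 0 higher and 4 lower in pEx5 (0 and 6 adjusted over the list alone; camera adjusted p = 0.0016; adjusted p = 0.248 with an estimated correlation). They were 0 and 9 in mEx5 (0 and 11 adjusted over the list alone; camera adjusted p = 8.47e-05; adjusted p = 0.295 with an estimated correlation). MYC and nucleolar targets were 0 higher and 11 lower in each line (0 and 11 adjusted over the list alone), Pes1 by a change of -0.24 ± 0.055 in pEx5 (camera adjusted p = 0.000141 in pEx5 and 0.000542 in mEx5; adjusted p = 0.199 and 0.295 with an estimated correlation). Neural splicing regulators were 7 higher and 0 lower in each line (8 and 7 higher adjusted over the list alone), Elavl2 by 0.56 ± 0.073 (camera adjusted p = 0.00161 and 0.0346; adjusted p = 0.248 and 0.471 with an estimated correlation). In pEx5 neuronal genes passed, with 10 higher and 0 lower (10 and 0 adjusted over the list alone; camera adjusted p = 0.000141; adjusted p = 0.145 with an estimated correlation). G2/M genes passed there with 1 higher and 12 lower (1 and 13 adjusted over the list alone; camera adjusted p = 0.000715; adjusted p = 0.198 with an estimated correlation). Interferon genes passed there with 0 and 2 (0 and 2 adjusted over the list alone; camera adjusted p = 0.0178; adjusted p = 0.248 with an estimated correlation). In mEx5 heat shock genes passed with 0 higher and 5 lower of 10 (0 and 6 adjusted over the list alone; camera adjusted p = 0.00279; adjusted p = 0.295 with an estimated correlation).

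Isoform-dependent induction, the difference of the induction effects between the lines, asked which events and genes respond to exon 5 of the cDNA. A 117 nt exon of the centriolar satellite gene Pcm1 went from 71.8 ± 1.2% to 39.1 ± 0.5% on induction in pEx5 and from 67.8 ± 0.6% to 74.3 ± 0.8% in mEx5 (SD, n = 2; weighted limma test, adjusted p = 0.000737). A 24 nt microexon of Picalm, a clathrin assembly gene, went from 23.5 ± 0.7% to 51.3 ± 0.6% in pEx5 and from 28.1 ± 2.2% to 32 ± 0.9% in mEx5 (adjusted p = 0.0214). A 45 nt alternative 3′ splice site of Serbp1 went from 42 ± 0.1% to 53.3 ± 0.9% and from 45.1 ± 0.1% to 35.3 ± 0.2% (adjusted p = 0.015). A 39 nt exon of the neuronal RNA-binding protein gene Elavl2 went from 24.5 ± 2.3% to 58.1 ± 3.8% in mEx5 and stood at 20.4 ± 0.6% and 22.5 ± 0.7% in pEx5 (adjusted p = 0.0148). A 445 nt alternative 3′ splice site of the septin gene Sept8 went from 89.1 ± 0.7% to 45.8 ± 5.5% in mEx5 and stood at 88.2 ± 0.9% and 81.2 ± 0.4% in pEx5 (adjusted p = 0.0133). A 295 nt exon of Pstk stood after induction at 53.6 ± 2.7% in mEx5 and at 15 ± 2.8% in pEx5 (adjusted p = 0.0214 for the difference of the induction effects). The weighted test called 8 events higher and 24 lower, 4 and 22 of them exons (exact binomial p = 0.000534 for the exons), while the planned limma test called 0 (9570 at an unadjusted p under 0.05). The higher exons include exon 5 of Puf60, in which the cDNAs differ by design (84.9 points, weighted limma test, adjusted p = 9.85e-07). The count of 32 was 6 without pEx5 knockdown library A, 6 without B, 5 without pEx5 induced library A, 11 without B, 6 without mEx5 knockdown library A, 6 without B and 20 without mEx5 induced library A. The excess of lower events was lost without mEx5 knockdown library A or B (3 of 6 higher) and turned without pEx5 induced library B (6 of 11 higher). Each cDNA was tested in 1 line, and the control lines differed as well, so properties of the line are part of each difference.

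Among genes, Ddx46 (ENSMUSG00000021500.17) stayed at its knockdown level in pEx5, with 594.4 ± 4.4 and 555.2 ± 28.6 CPM, and returned from 572.5 ± 10.8 to 267.3 ± 8 CPM in mEx5, where controls had 297.4 ± 10.8 (SD, n = 2; log2 difference 1 ± 0.07, limma adjusted p = 1.4e-07). Ift20, an intraflagellar transport gene, returned from 26.6 ± 1.8 to 52.3 ± 2.1 CPM in mEx5 and went from 28.9 ± 0.7 to 20.6 ± 0.4 in pEx5 (-1.46 ± 0.11, limma adjusted p = 1.4e-07). Pdia5 had a log2 difference of 0.93 ± 0.09 (limma adjusted p = 5.79e-06), Prkca 0.73 ± 0.1 (0.00144), Clk3, a kinase of SR proteins, -0.66 ± 0.09 (0.00206), Zdhhc4 -1.02 ± 0.16 (0.00346) and the RNA-binding protein gene Rbm4 -1.01 ± 0.16 (0.00395). Limma on junction reads called 50 genes higher and 28 lower in pEx5. Puf60 itself had a difference of 0.32 ± 0.084 (adjusted p = 0.0755). Neuronal genes were 3 higher and 0 lower of 29 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00175; adjusted p = 0.224 with an estimated correlation). G2/M genes passed with 0 single genes called either way and a median of -0.09 (0 adjusted over the list alone; camera adjusted p = 0.00175; adjusted p = 0.224 with an estimated correlation). The count of 78 was 17 without pEx5 knockdown library A, 19 without B, 23 without pEx5 induced library A, 20 without B and 44 without mEx5 induced library B.

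The control libraries of the lines asked how far the lines differ without knockdown. Among the genes lower in pEx5 were Sparc, an extracellular matrix protein gene, with a log2 change of -2.98 ± 0.069 (SE, n = 2 per group; limma adjusted p = 1.76e-16), Rbpms with -3.55 ± 0.15 (1.37e-12) and Acta2, a smooth muscle actin gene, with -5.18 ± 0.27 (3.36e-11). Actg2 (ENSMUSG00000059430.14) had -4.31 in the authors' deposited table and -0.65 ± 0.052 on junction reads (limma adjusted p = 1.74e-08). Of the neuronal list, Dbh and Th, genes of noradrenaline synthesis, were higher in pEx5, with Dbh at 1.73 ± 0.13 and Th at 1.93 ± 0.41 (limma adjusted p = 1e-08 and 0.00142), and Htr3a at 1.78 ± 0.069 (5.26e-13). The other named genes in the authors' deposited table were Elovl7 (1.5), Pnpla3 (1.45), Syt17 (1.44), Ccnb1ip1 (1.43), Fam107b (-3.3) and Enpp3 (-2.57). The authors' deposited table called 2264 genes higher and 2231 lower in pEx5, of which 129 and 747 differed at least 2-fold. On junction reads limma called 1378 and 1427, and the count of 2805 was 1698 without mEx5 control library A, 1739 without B and 1803 without pEx5 control library B. The balance was close to even, with 1497 higher of 2975 without mEx5 induced library A and 1494 without B, and it depended on the scaling: with total junction reads 938 were higher and 1717 lower.

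Cholesterol synthesis genes were higher in pEx5 controls, with 16 higher and 0 lower of 19 (17 and 0 adjusted over the list alone), Insig1 at 0.84 ± 0.13 and Lss at 0.8 ± 0.062 (camera adjusted p = 9.77e-14; adjusted p = 0.0883 with an estimated correlation). Integrated stress response genes were 15 higher and 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 6.09e-07; adjusted p = 0.0883 with an estimated correlation), Atf3 at 0.78 ± 0.14. Glial and fibroblast markers were 0 higher and 3 lower of 6 (0 and 3 adjusted over the list alone; camera adjusted p = 0.00245; adjusted p = 0.1 with an estimated correlation), Pdgfra at -1.77 ± 0.18. Interferon genes were 1 higher and 6 lower (1 and 7 adjusted over the list alone; camera adjusted p = 0.0219; adjusted p = 0.333 with an estimated correlation), Isg15 at -1.64 ± 0.18. Hypoxia genes were 8 and 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0194; adjusted p = 0.193 with an estimated correlation). MYC targets were 5 and 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0194; adjusted p = 0.355 with an estimated correlation). Nuclear respiratory chain genes were 7 and 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0219; adjusted p = 0.69 with an estimated correlation). Unfolded protein response genes were 7 and 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0257; adjusted p = 0.333 with an estimated correlation).

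Single splicing events differed between the control lines. A 4125 nt intron of Bdh2 was retained at 100 ± 0% in pEx5 and 70.6 ± 3.5% in mEx5 (SD, n = 2; planned limma test, adjusted p = 0.0047). A 53 nt exon of Copg2 was at 89.5 ± 1.4% and 100 ± 0% (adjusted p = 0.00589), and a 47 nt alternative 3′ splice site of Rad51ap1 at 0 ± 0% and 13.4 ± 6.7% (adjusted p = 0.0123). These 3 events were the planned calls (10346 at an unadjusted p under 0.05), and the weighted test called 3 higher and 14 lower, among them Cux1 (18.6 points), Hp1bp3 (11.6), Evi5l (-35), Stag1 (-27.2) and Epb4.1l2 (-27.1). Without pEx5 control library B the weighted test called 8 higher and 6 lower. The authors' deposited table called 126 higher and 133 lower at 10 points or more. On simulated knockdown the planned test recovered 0 of 50 changes of 30 points, so its 3 calls are no measure of how little the lines differed. The planned count was 0 without any 1 of the 4 control libraries and 5 without either mEx5 induced library.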

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

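The tests of Puf60 level and read depth, of normalization and collagen genes in the control lines, and of the 3 explanations for exon 5 were chosen only after the result was seen, as were the weighted test and the junction-read tests behind the values of this part; exon 5 inclusion itself was a planned result.

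Effects that differed between the lines were picked out by a test of the difference itself: 32 events in the weighted test and 78 genes on junction reads for induction, and 3 genes for knockdown. The 32 events include exon 5 of Puf60 itself (84.9 points), in which the cDNAs differ by design. The 3 knockdown genes were Cth (log2 difference -0.78 ± 0.086, limma adjusted p = 0.000282), Htr3a (-0.63 ± 0.098, 0.0211) and Capn6 (-0.67 ± 0.11, 0.0383), named after their values were seen. Without 1 library the 32 events were 6 (pEx5 knockdown A), 6 (B), 5 (pEx5 induced A), 11 (B), 6 (mEx5 knockdown A), 6 (B) and 20 (mEx5 induced A), and the 78 genes were 17 and 19 (pEx5 knockdown A and B), 23 and 20 (pEx5 induced A and B) and 44 (mEx5 induced B). Events with a more positive change on induction in pEx5 were a BC018507 intron (113.5 points, with as few as 10 reads), Sept8 (36.3), Ivns1abp (24.8), Picalm (23.9), Serbp1 (21.2), Rbck1 (18.4) and Mdm1 (16). Events with a more negative change there were in Pcm1 (-39.2 points), Pstk (-38.3), Sept8 (-38.1), Elavl2 (-31.6), Zc3h11a (-28), Ifi27l1 (-26.3), Tmpo (-24.8), Rnf14 (-22.7) and Nipa1 (-21). Genes with a more positive log2 change on induction in pEx5 were Ahnak (1.38), Blcap (1.07), Ddx46 (1), Pdia5 (0.93), Dbh (0.91), Parp3 (0.88), Sez6 (0.84), Taz (0.8), Myo18b (0.8) and Prkca (0.73). Those with a more negative one were Ift20 (-1.46), Zdhhc4 (-1.02), Rbm4 (-1.01), Bbs2 (-0.68), Cyb5r2 (-0.67), Fastkd3 (-0.67), Clk3 (-0.66), Gnptab (-0.59), Fam175a (-0.55) and Chid1 (-0.52). For Ahnak the log2 ratios of group RPKM in the authors' deposited table were 0.5 and -0.15 on induction.

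More exons rose on induction in mEx5 than in pEx5, 1184 against 818 in the weighted test, but over all types the order of higher events turned without mEx5 knockdown library A (942 against 950), without B (935 against 955) and without mEx5 induced library A (1051 against 1082). Fewer reads in pEx5 libraries are argued against, since the mean depth of its knockdown and induced libraries was 1.14 times that of mEx5. Equal restoration with calls set by the threshold is not decided. The rescue intervals of the lines, over events of the weighted test, were 13.7 points apart. They come from draws over events and do not measure the spread between cultures or lines. The events also differed, with 2767 for pEx5 and 3300 for mEx5. Puf60 RNA in induced libraries was not lower in pEx5 on average, at 624.4 ± 9.8 against 601.8 ± 32.5 CPM (SD, n = 2; log2 difference 0.05 ± 0.059, limma adjusted p = 0.507), but a slightly lower level stays open, since the lowest of the 4 ratios between libraries was 0.99. The lack of exon 5 in the cDNA may account for the difference, but each cDNA was in 1 line, so the line and its isoform were not separated.

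In the authors' deposited table, genes at least 2-fold lower outnumbered those at least 2-fold higher in pEx5 controls. A shift of the normalization is not decided. Relative to the median of all genes the ratio of called lower to higher genes was 5.93, but that median was already 0.009, so centring on it could change little. Gain or loss of whole chromosomes is argued against. Chromosome medians ran from -0.129 (chromosome 2) to 0.135 (chromosome 18), none reached the limit of 0.3, and thus 0% of the lower genes lay on shifted chromosomes. Fibroblasts among the mEx5 cells are argued against by collagen genes Col1a1, Col1a2 and Col3a1, none above 0.03 RPKM in mEx5 controls in the authors' deposited table. Other glial or mesenchymal cells stay open: the marker list had a median log2 change of -1.12 over the 6 of its 28 genes measured on junction reads, and of -1.05 over 15 genes in the authors' deposited table, with 0 higher and 5 lower, so that many of its genes were not measured. A clonal difference between the lines is a candidate explanation that was not tested.

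Inclusion of Puf60 exon 5 fell on knockdown in both lines by the weighted test. Uninduced expression of the cDNA would raise it in pEx5, where it changed by -15.9 points, and counting error is argued against by intervals that lay apart in 8 of 8 pairs of knockdown and control libraries. An siRNA site within exon 5 is argued against by the recoding primer of the cDNA, which shares 14 nt with the end of the coding sequence. Whether the siRNA lowers transcripts with and without exon 5 alike was not tested. A candidate explanation is that Puf60 promotes inclusion of its own exon 5. Different stability of the isoforms was not tested.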

How the results depend on the processing

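The weighted test, the weights, the mean PSI range, the authors' calls as an alternative and junction reads as the source of gene values were chosen only after the result was seen; the gene-list tests and the correlation between lines, made on those values, were planned. Of the values recomputed under alternatives, 280 kept their side of the threshold or, for counts, stayed within 1.5 times, 157 counts or shares moved by more than 1.5 times or their spread, and 7 newly passed a threshold. No change or share turned its sign, but the balance of higher and lower calls turned for weighted control lines without pEx5 control library B (8 of 14 higher), weighted isoform-dependent induction without pEx5 induced library B (6 of 11) and planned control lines at 15 points (1 of 1). It also turned without single libraries for junction-read counts near balance, namely knockdown in each line, induction in mEx5 and control lines. With total junction reads as the scaling the median of all genes moved from 0.01 to 0.04 for knockdown in both lines (3150 higher and 2292 lower) and from 0.01 to -0.03 for control lines (938 and 1717). The cause was not tested unless stated. In the simulation, where far fewer events changed than on the real knockdown, the planned test recovered 0 of 50 changes of 30 points. With the same libraries and depth a mean PSI of 5 to 95 recovered 43, weights alone 41 and both 49. Depth limits which events were tested, those with at least 10 reads in each library.

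Leaving out 1 library leaves fewer residual degrees of freedom. The planned splicing counts then ran from 1377 to 2090 for knockdown in both lines, 109 to 718 in pEx5 and 0 to 540 in mEx5, 0 to 0 for induction in pEx5 and 0 to 99 in mEx5, 0 to 0 for isoform-dependent induction and 0 to 5 for control lines; the libraries that moved them stand beside the counts in the results. In the same order the weighted counts ran from 3540 to 3885, 2418 to 3315, 1883 to 2797, 736 to 1364, 1218 to 2070, 5 to 36 and 13 to 19, and the junction-read counts from 4728 to 5570, 2927 to 4250, 2606 to 3931, 1124 to 2457, 1869 to 2707, 17 to 91 and 1698 to 2975. Rescue shares ran from 77.4 to 80.3% in pEx5 and 89.4 to 92.5% in mEx5; without mEx5 knockdown library A or B no event was called there and the pEx5 share had no value.

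For knockdown in pEx5 and mEx5, induction in pEx5 and mEx5, isoform-dependent induction and control lines, the planned splicing counts became 1471, 1172, 157, 541, 1 and 5 with a pseudocount of 1. On the PSI scale the first 5 of these were 2087, 1966, 1045, 1710 and 39. With a mean PSI of 5 to 95 they were 2718, 2601, 1115, 1947, 43 and 13, and 3648 for both lines. With weights alone they were 2344, 1741, 668, 1056, 6 and 10. With both, which is the weighted test, they were 3301, 2768, 1311, 2056, 32 and 17, and 3876 for both lines. The authors' calls in the authors' deposited table gave 2857, 2536, 1758, 2283 and, for control lines, 259. With the replicate letter as a block the planned counts were 555, 398, 0 and 2 for knockdown and induction in pEx5 and mEx5. Differences between replicates A and B had a median correlation of -0.02 across pairs of groups on genes (-0.13 to 0.16). The highest was between mEx5 control and mEx5 knockdown, where it was 0.01 on splicing. The letters thus showed no common pairing, but pairing within a line is not excluded. A minimum of 20 reads gave 28 for induction in pEx5, and a threshold of 15 points gave 1 for control lines, and in the weighted test 2350 for knockdown in both lines and 1360 for induction in mEx5.

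Genes called on junction reads numbered 3714 for knockdown in mEx5, 2275 for induction in pEx5 and 2805 for control lines, and with the block 3680, 2245 and 2744. Rescue shares in pEx5 and mEx5 were 81.6 and 97.5% with events called by adjusted p alone, 69.1 and 83.5% as means, 66.5 and 83.5% over weighted calls, and 43.8 and 61.1% over genes. The correlation between lines was 0.724 over all planned events and 0.84 over all genes, against 0.92 and 0.896 over those called in either line. Under the weighted test 43.5% of alternative 3′ and 30.5% of 5′ splice sites were lower, and changes of Puf60 exon 5 passed that the planned test did not call (-15.8 points in both lines, -15.9 in pEx5, -15.6 in mEx5, -17.7 on induction in mEx5 and 84.9 for isoform-dependent induction). With an estimated correlation 0 gene lists passed in each comparison but knockdown in mEx5, where 2 did. Not run were the expression alternatives that need values per library (DESeq2, edgeR, other normalizations, filters and pseudocounts) and the features of 3′ splice sites.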

Other observations

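The junction-read tests and the weighted test of this part were chosen only after the result was seen.

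In a principal component analysis of gene levels the first component, with 52.3% of the variance, separated the lines, the second, with 22.1%, ran from control to knockdown, and the third, with 9.7%, set induced libraries apart. Acta2 and Myl9, which were lower in pEx5 controls, rose on knockdown, Acta2 by 1.64 ± 0.19 on the log2 scale in both lines (SE, n = 2 per group; limma adjusted p = 5.96e-07) and Myl9 by 2.61 ± 0.093, while Sparc rose by 0.57 ± 0.049 (adjusted p = 8.76e-09). Acta2 is near the floor in pEx5 controls, at 0.07 RPKM in the authors' deposited table.

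Single members of lists that did not pass as groups also moved. Adm, a secreted vasodilator peptide gene, rose on knockdown by 1.96 ± 0.24 (log2, SE, n = 2 per group; limma adjusted p = 1.36e-06) and Klf6 by 0.7 ± 0.051 (1.28e-09), while Egr1 changed by -0.93 ± 0.13 (3.84e-06).

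A hypothesis written before its test was that genes lose mRNA when a skipped exon shifts the reading frame. Changes were the authors' deposited log2 fold changes on knockdown, averaged over the lines. Their median was -0.18 in 429 genes whose skipped exons have lengths not divisible by 3. It was -0.097 in 437 genes with divisible lengths, a difference of -0.083 (permutation p = 5e-05). With the events of the weighted test the medians were -0.143 in 597 genes and -0.08 in 612, a difference of -0.063 (permutation p = 0.00024). These values are consistent with some loss of frame-shifted mRNA, which may act through nonsense-mediated decay. Decay was not measured.

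The knockdown counts of both lines were set against other splits of the 8 uninduced libraries. Of the 35 splits, 34 could be fitted with the line as a term, and 1 of the splits, the real one, gave as many calls in each test. Restricted to these libraries, the planned splicing test called 1943 events against at most 0 in the other splits, the weighted test 3933 against 0, and junction reads 5526 genes against 0. Chance can be excluded for each only at the smallest share these splits allow. The other splits put knockdown and control libraries on both sides, which widens their spread, so their counts of 0 do not measure how often the tests call by chance.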
